A study of Homo sapiens with 4 samples.

How the data were processed

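RNA was taken from MCF7 cells 48 h after nucleofection with control siRNA (2 samples) or CEBPD siRNA (2 samples) and sequenced as paired ends on an Illumina HiSeq instrument, per the labels' protocols. The siRNA sequences and their number are not given in the sources used here. The deposited table holds RPKM (read counts divided by gene length and by library depth), as its name says, for 16381 gene symbols. The submitters' processing notes name the genome build hg19, CASAVA 1.8.2, Partek without a version and GenomeStudio 6.6, without saying what each did. The aligner's settings, the gene annotation and the counting by strand are not given in the sources used here. The table runs alphabetically and ends within the letter S, so genes later in the alphabet were not analysed here. In it 27 symbols had been turned into dates by a spreadsheet, and these stayed in the tests without being named.

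Each row of the table was given a group from its name. The row names carry the numbers 2 and 3 while the labels number the replicates otherwise, so a row's group is known and which sample of the group it is stays open. RPKM is already scaled for gene length and depth by the authors, so no further scaling was applied. Depth was judged from the low values. Of 1682 genes at or under 0.05 RPKM, 1248 (74.2%, within a tolerance of 0.03 of a step) lay on whole multiples of a common step, against 0.1% for values without steps. Relative to control siRNA library 2 the depths were 1.1883 for control siRNA library 3, 1.0749 for CEBPD siRNA library 2 and 1.1482 for CEBPD siRNA library 3. Absolute depths are estimates, since they use transcript lengths of the GENCODE annotation and not those of the authors. Replicates differed by more than counting noise, with a spread 1.28 to 3.64 times that of counting between the controls and 1.29 to 2.6 times between the CEBPD siRNA libraries, so all 4 libraries were counted separately.

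Genes entered the tests if their mean RPKM over the 4 libraries was at least 0.5, which left 9810. Values were tested as log2(RPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A fold change is on the log2(RPKM + 0.5) scale, which understates the change of low genes. The residual degrees of freedom were 2 and the prior contributed 7.68. Genes at least 1.5-fold apart with no overlap between groups were counted without a test. Gene lists were compared with the other genes by camera with its preset correlation of 0.01, adjusted over the 28 lists with at least 5 tested members, out of 32 lists fixed before the data were examined. They hold 821 genes, of which 687 are in the table and 565 were tested. The lists covered the C/EBP family and its described targets, the cell cycle, p53, epithelial and mesenchymal genes, oestrogen response, inflammation and interferon, metabolism, stress, apoptosis, RNA interference, ribosomal and histone genes, RNA quality and markers of other cell types.

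Genes named were chosen by a rule set at the same time. It takes CEBPD with its family and SNAI2, the 12 largest rises and 12 largest falls among genes past the threshold without overlap between groups (symbols of uncharacterised loci and small RNAs were passed over), up to 4 members of each list described, and the described C/EBPδ targets. It names 143 genes. Exons of 52 of them overlap those of another annotated gene, and without stated strand their reads cannot be told apart. Gene positions, transcript lengths, GC content, 3′ UTRs and promoters came from GENCODE release 44 on GRCh37, the same assembly as hg19, to which 13975 symbols matched directly and 1196 through synonyms, with 1210 unmatched. Of the genes tested 9426 (96.1%) had a length and GC content.

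The tests were checked on simulated data, 9810 genes with 200 changed by known folds. The noise was drawn as independent normal values with limma's own variances, so the model's assumptions were met by design. The shares below therefore do not give the rate of false calls among the real genes. For the comparison of CEBPD siRNA with control siRNA, 42% of genes changed by 1.1-fold and 100% of those changed by 1.25-fold, 1.5-fold and 2-fold were recovered, 3.93% of calls were false, and 2 genes were called where nothing changed. Alternatives were other pseudocounts (0.1 and 1), no filter or a mean RPKM of at least 2, other scalings, other variance models, a replicate block, a correction for GC content and length (loess), each library left out, and other set tests. Camera with an estimated correlation takes its p-values with the 2 residual degrees of freedom, so it could hardly call any list. The block by the table's numbers and the correction without a block were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for the sequence tests and matplotlib 3.10.9 for the figures.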

Results

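RNA was sequenced from MCF7 cells, an oestrogen receptor-positive luminal breast cancer cell line, 48 h after nucleofection with control siRNA or with siRNA against CEBPD. CEBPD encodes C/EBPδ, a basic leucine zipper transcription factor of the CCAAT/enhancer-binding protein family. The series asks which genes CEBPD regulates in these cells. There were 4 libraries, 2 with control siRNA and 2 with CEBPD siRNA, and the deposited values were RPKM for 16381 gene symbols. The libraries carry the numbers 2 and 3 in the deposited table, and these numbers are used here as names. RPKM summed to between 141921 and 144654 per library. Of 1682 genes at or under 0.05 RPKM, 74.2% lay within 0.03 of a whole step, and from these steps an estimated 135300000 and 160700000 reads or read pairs lay behind control siRNA libraries 2 and 3, and 145400000 and 155300000 behind CEBPD siRNA libraries 2 and 3. Nothing in the labels says that the replicates came from separate cultures, so every p-value measures the spread between these libraries, which may be technical.

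CEBPD itself was lower in both libraries that received CEBPD siRNA. Its transcript level was 6.69 ± 0.142 RPKM (SD, n = 2) with control siRNA and 2.35 ± 0.576 RPKM (SD, n = 2) with CEBPD siRNA, which is 35.2% of the control mean. The single libraries gave 6.79 and 6.59 RPKM with control siRNA and 2.76 and 1.95 RPKM with CEBPD siRNA. CEBPD fell by 1.35 on the log2(RPKM + 0.5) scale (SE 0.103, limma adjusted p = 2.4e-05). CEBPD is an intronless gene on chromosome 8, from 48649475 to 48650726 on the minus strand of GRCh37, with 1 exon of 1252 nt. The levels stand for an estimated mean of 1238 reads with control siRNA and 440 with CEBPD siRNA. The fall was past the threshold under every alternative setting computed for it.

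**Figure D1:**
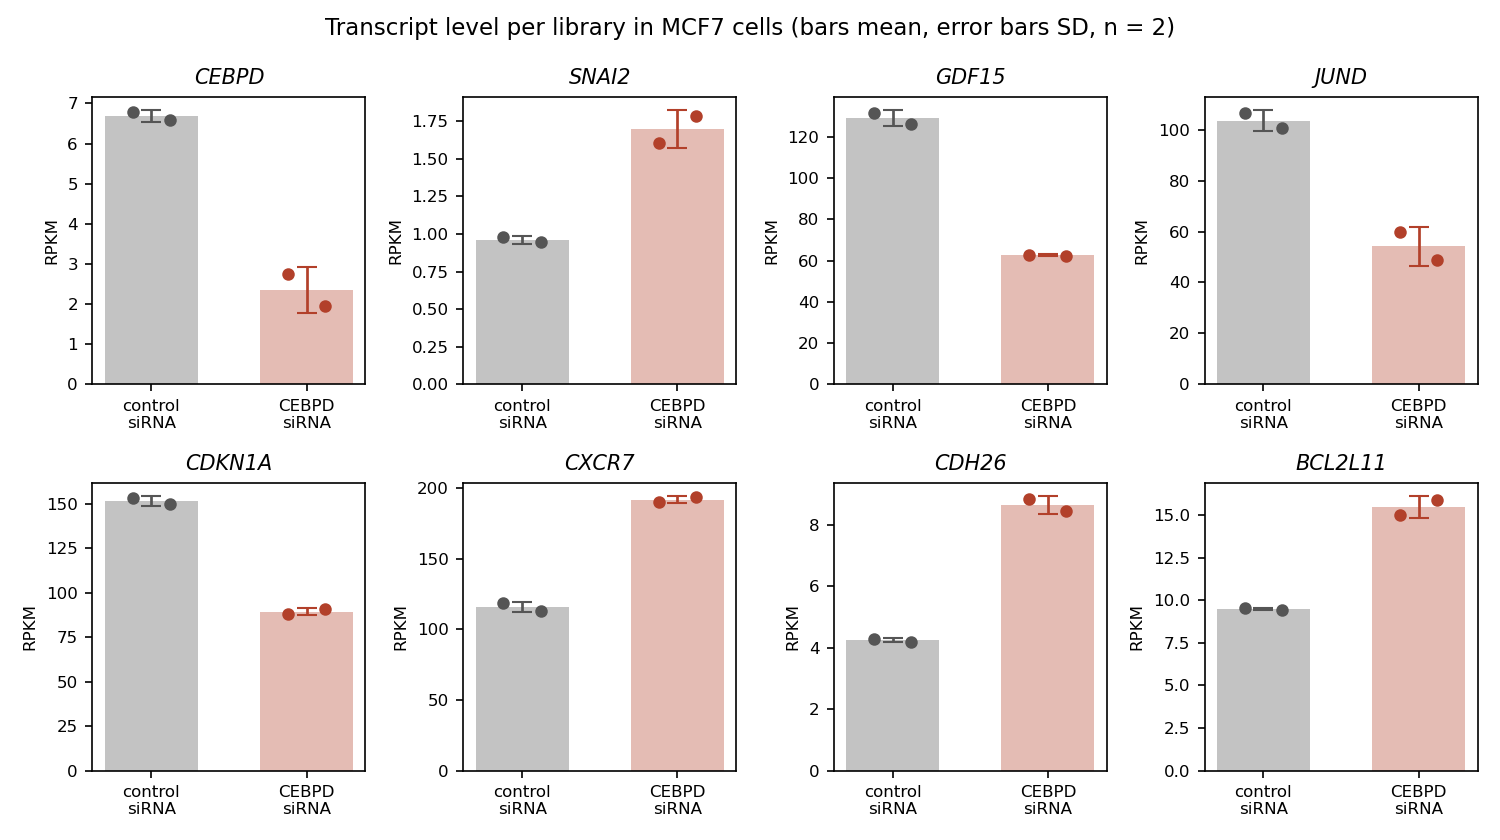
Transcript levels in RPKM (vertical axes, from 0) of 8 genes in the control siRNA and CEBPD siRNA libraries. Points are libraries, bars the mean and error bars the SD (n = 2). CEBPD lies at 6.79 and 6.59 RPKM with control siRNA and at 2.76 and 1.95 RPKM with CEBPD siRNA, and in each of the other panels both CEBPD siRNA points lie on the same side of both control points.

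Knockdown was accompanied by many changes of small size. Of the 9810 genes tested, 3376 (34.4%) passed the threshold in limma (adjusted p under 0.05), 1602 of them higher and 1774 lower with CEBPD siRNA, and 4403 had an unadjusted p under 0.05. The median size of the change among the genes that passed was 0.19 on the log2 scale, and 2563 of them (75.9%) changed by less than 1.2-fold. On the log2(RPKM + 0.5) scale only MIF, CEBPD and GDF15, 3 genes, passed with a change of at least 2-fold. In RPKM itself further genes changed by that much, among them CDH26 (204% of the control mean), ROM1 (215%), ACTL8 (208%) and LHFP (37.7%). Without a variance model, 66 genes had group means at least 1.5-fold apart and no overlap between groups, 25 of them higher and 41 lower with CEBPD siRNA. These counts depend on the pseudocount, with 140 genes (57 higher, 83 lower) at 0.1 and 34 (11 and 23) at 1, and a mean RPKM of at least 2 left 13 higher. Groups did not overlap for 6757 genes (68.9%), where chance alone gives 33.3%. The 2 control libraries differed with an SD of 0.0745 over genes on the log2 scale, and the 2 CEBPD siRNA libraries with an SD of 0.0709. Pearson's r across genes, which are not independent replicates, was 0.99899 and 0.99909 within groups and between 0.99420 and 0.99561 across groups. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333, so the calls rest on the spread that limma shares between genes. The share of higher genes among those that passed, 47.5% here, depended on the scaling. It was 54.3% of 3579 with values scaled to equal sums, 51.6% of 3404 with quantile normalization, 47.7% of 3515 with median centring and 51.6% of 3904 after a correction for GC content and length. With no filter on low values the count was 1876, and without control siRNA library 2 the number of higher genes was 1032.

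Genes with diverse functions led the rises. CDH26, which encodes an atypical cadherin, rose from 4.24 ± 0.0606 to 8.65 ± 0.28 RPKM (SD, n = 2 in each group), a log2 change of 0.95 (SE 0.0393, limma adjusted p = 1.5e-06). CXCR7, the atypical chemokine receptor now named ACKR3, was the most abundant gene among the 12 largest rises and went from 116 ± 3.73 to 192 ± 2.2 RPKM (log2 change 0.73). The imprinted long noncoding RNA H19 rose from 53.9 to 92.8 RPKM (log2 change 0.78), and BCL2L11, which encodes the pro-apoptotic protein BIM, rose from 9.47 to 15.5 RPKM (log2 change 0.68). ROM1 rose by 0.91, ACTL8 by 0.87, SUSD2 by 0.76 and SUSD3 by 0.74 on the log2 scale. MAFB, a transcription factor of monocytes among other cells, rose by 0.71, and CYP24A1, the vitamin D 24-hydroxylase, by 0.69. CDC42EP2 and AFAP1L2 rose by 0.67 and 0.66. CDH26 lies at 58533478 to 58609066 on chromosome 20 and CXCR7 at 237476430 to 237490997 on chromosome 2 (GRCh37). Limma's adjusted p for these 12 genes was at most 7.5e-05, and both CEBPD siRNA libraries lay above both controls for each.

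After MIF and CEBPD, GDF15 had the largest fall among the genes that passed. GDF15, a stress-induced cytokine of the TGF-β superfamily, fell from 129 ± 3.86 to 62.5 ± 0.471 RPKM (SD, n = 2 in each group), a log2 change of −1.04 (SE 0.0319, limma adjusted p = 3.2e-07). JUND, a subunit of the AP-1 transcription factor, fell from 104 ± 4.15 to 54.3 ± 7.65 RPKM (log2 change −0.93, SE 0.0733, limma adjusted p = 2.9e-05). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, fell from 152 ± 2.56 to 89.2 ± 1.98 RPKM (log2 change −0.76), and SERPINA3, the acute-phase protease inhibitor α1-antichymotrypsin, from 70.0 ± 2.82 to 39.8 ± 0.474 RPKM (log2 change −0.81). FBXL16 fell by 0.89, LHFP by 0.88, PPP6R1 by 0.88, SLC9A3R2 by 0.79, PSCA by 0.76 and ANG by 0.74 on the log2 scale. MIF had the largest estimate, −1.55 (SE 0.345, limma adjusted p = 0.0075), at 5.39 and 2.71 RPKM with control siRNA and 1.76 and 0.468 RPKM with CEBPD siRNA. Its call ended without control siRNA library 2 (adjusted p = 0.064), with robust hyperparameters (0.256) and without the filter (0.137), and its estimate was −0.944 without CEBPD siRNA library 3. GDF15 and JUND lie on chromosome 19 of GRCh37, at 18485541 to 18499986 and 18390504 to 18392432, and CDKN1A lies at 36644237 to 36655114 on chromosome 6. Exons of MIF, FBXL16, PPP6R1, SERPINA3, ANG and, among the rises, CDC42EP2 overlap those of another annotated gene, and no source used here says whether reads were counted by strand.

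Genes that fell held some short sequences in their 3′ untranslated regions more often than the rest, found after the data were examined. The 3 words were picked as the lowest among the 7-base words searched on these same changes. A higher share among the falls therefore follows in part from that choice, which the interval ignores. The shares are also not adjusted for 3′ UTR length or GC content, whereas the scan under the other observations is. Of the 1611 genes that fell and have an annotated 3′ UTR, 715 (44.4%, 95% Wilson interval 42.0 to 46.8%) held at least 1 of the 7-base words GAGAGAA, AGAGAGA and TGAGAGA, against 1741 of the 5862 genes that did not pass (29.7%) and 388 of the 1516 that rose (25.6%). CEBPD, JUND, FBXL16, LHFP, PPP6R1 and SLC9A3R2 were among the genes that fell with such a word, and MIF, GDF15, CDKN1A, SERPINA3, PSCA and ANG held none of the 3 words. MAFB and SNAI2, which rose, also held them.

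**Figure D2:**
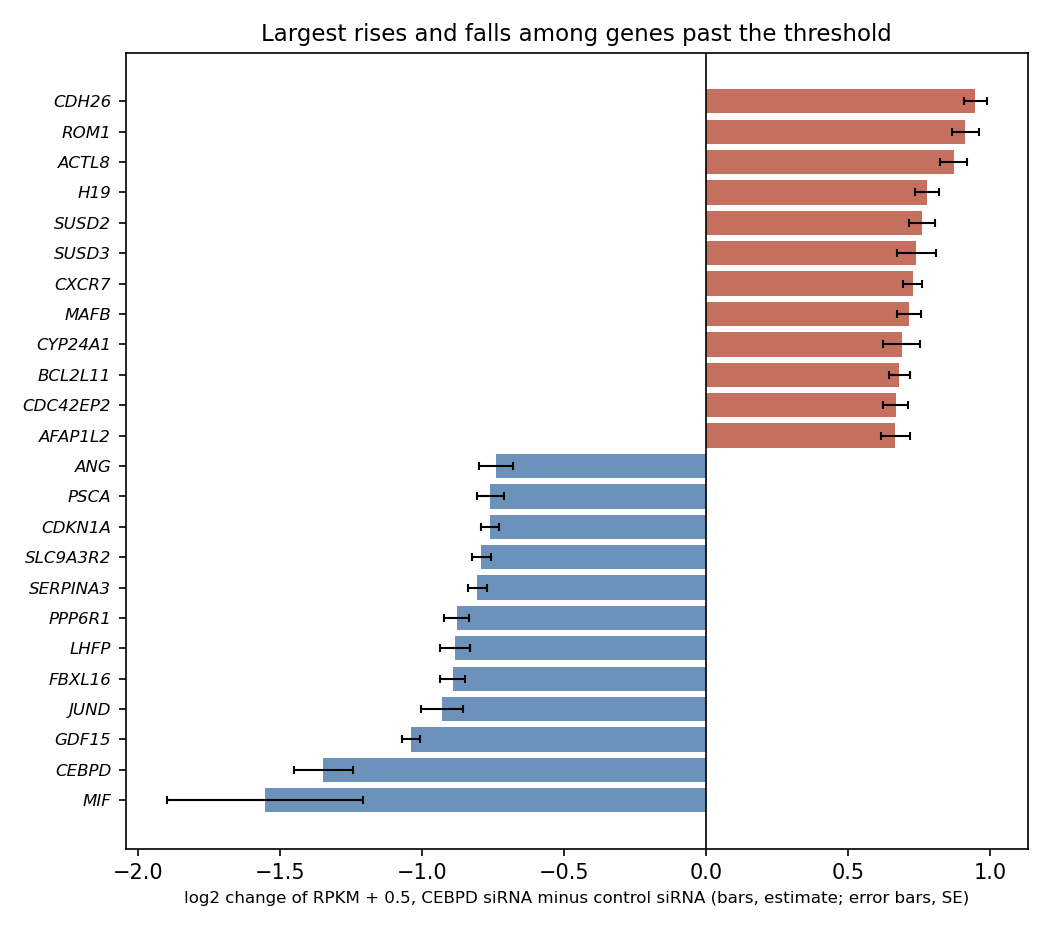
Log2 change of RPKM + 0.5, CEBPD siRNA minus control siRNA (horizontal axis), for the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap. Bars are limma estimates and error bars their SE (n = 2 in each group). The rises end at 0.95 for CDH26, and the falls reach −1.35 for CEBPD and −1.55 for MIF, whose SE of 0.345 is the widest of the 24 shown.

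Other members of the C/EBP family changed little beside CEBPD. DDIT3, which encodes the stress-induced family member CHOP, fell from 9.79 to 8.60 RPKM (log2 change −0.18, limma adjusted p = 0.0048). CEBPB was at 37.8 ± 2.8 and 34.5 ± 3.6 RPKM (SD, n = 2 in each group; log2 change −0.13, limma adjusted p = 0.15). With 1 library left out its log2 change ranged from −0.24, without CEBPD siRNA library 2, to −0.026. The log2 changes of CEBPA (−0.06), CEBPG (−0.03) and CEBPZ (0.08) did not pass, and those of CEBPA and CEBPG changed sign when 1 library was left out, to 0.00414 without control siRNA library 2 and 0.00598 without control siRNA library 3. Of the 6 genes tested on the family list, which includes CEBPD, 0 rose, 2 fell (CEBPD and DDIT3) and 4 did not pass. The counts adjusted over the list alone were the same. Camera's adjusted p for the list was 0.13, which is not a test of the other members, since CEBPD is among them. CEBPZ is on the list by name, although it is not a basic leucine zipper factor.

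Genes described in the literature as C/EBPδ targets moved in both directions. Of 18 tested, 5 rose, 6 fell and 7 did not pass, also when adjusted over the list alone, and camera's adjusted p was 0.70. Of all genes tested 34.4% passed. The list was not sorted by the reported direction of regulation and camera looks for a shared direction, so its value does not tell whether the targets responded. SNAI2, the transcription factor SLUG of the epithelial-mesenchymal transition, rose from 0.963 ± 0.0266 to 1.70 ± 0.126 RPKM (SD, n = 2 in each group; log2 change 0.59, SE 0.0554, limma adjusted p = 7.4e-05). It lies at 49830157 to 49834299 on chromosome 8 of GRCh37, on the minus strand. CCNE1, which encodes cyclin E1, rose by 0.29, MYC by 0.27, HIF1A by 0.24 and SOD1 by 0.10 on the log2 scale. CCND1, which encodes cyclin D1, fell from 171 to 140 RPKM (log2 change −0.29), and CXCR4 fell by 0.29, GADD45A by 0.28, IL6R by 0.24, BCL6 by 0.23 and PLK1 by 0.11. The log2 changes of FBXW7 (0.01), FANCD2 (−0.04), IPO4 (−0.06), CDC27 (0.03), MTOR (−0.04) and NOTCH1 (−0.02) did not pass. SOD1 did not pass without control siRNA library 2, CEBPD siRNA library 2 or CEBPD siRNA library 3 (adjusted p = 0.121, 0.173 and 0.0651), BCL6 not without control siRNA library 2 or CEBPD siRNA library 2 (0.0529 and 0.0571), and PLK1 not without control siRNA library 2, control siRNA library 3 or CEBPD siRNA library 3 (0.126, 0.0589 and 0.286, with a log2 change of −0.0697 in the last). Without the filter on low values SOD1, BCL6, PLK1 and IL6R did not pass (adjusted p = 0.0707, 0.0893, 0.112 and 0.0606), and without a variance trend SOD1 and PLK1 did not (0.0809 and 0.0815).

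Cell cycle inhibitors and p53 target genes fell as a group, and genes of the G1/S transition rose. Of 21 tested inhibitors and p53 targets, 16 fell, 2 rose and 3 did not pass, and the counts adjusted over the list alone were the same. The median log2 change was −0.28 (camera adjusted p = 1.7e-06, adjusted p = 0.604 with an estimated correlation). Besides CDKN1A, SPATA18 fell from 2.23 to 1.32 RPKM (log2 change −0.59), the antiproliferative gene BTG2 from 19.96 to 13.66 RPKM (−0.53) and CDKN2B, which encodes the kinase inhibitor p15, from 8.19 to 5.597 RPKM (−0.51). Of 27 G1/S genes, 14 rose, 0 fell and 13 did not pass, with 17 rising when adjusted over the list alone. Their median log2 change was 0.11 (camera adjusted p = 1.7e-05, adjusted p = 0.604 with an estimated correlation). Examples are CCNE1, from 3.75 to 4.67 RPKM, MCM4, a subunit of the replicative helicase, from 26.2 to 30.0 RPKM, and DHFR, the dihydrofolate reductase, from 8.34 to 9.67 RPKM. Limma's adjusted p of these genes was at most 0.0031.

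Genes of the Fanconi anaemia and homologous recombination pathways rose on balance, whereas the G2/M list was not called. Of 25 tested Fanconi anaemia and recombination genes 8 rose, 1 fell and 16 did not pass (9 rose and 1 fell when adjusted over the list alone), with a median log2 change of 0.11. Camera's adjusted p was 0.016 (adjusted p = 0.605 with an estimated correlation), and the call ended without control siRNA library 2, where the median was 0.0646 (adjusted p = 0.0627). The helicase genes BLM and BRIP1 rose by 0.21 and 0.20, and RAD54L by 0.22 on the log2 scale, and without the filter on low values BRIP1 and RAD54L did not pass (adjusted p = 0.0514 and 0.0643). Among 30 G2/M genes 2 rose, 3 fell and 25 did not pass (1 and 2 when adjusted over the list alone), and camera's adjusted p was 0.91. FOXM1, a transcription factor of that phase, rose from 38.8 to 45.3 RPKM (log2 change 0.22), and BIRC5, which encodes survivin, fell from 27.1 to 24.0 RPKM (−0.17).

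Immediate-early genes, which growth factors and stress induce within minutes, were mostly lower with CEBPD siRNA. Of 27 tested, 17 fell, 1 rose and 9 did not pass (18 fell and 1 rose when adjusted over the list alone), and the median log2 change was −0.20. The list was called by camera (adjusted p = 2.2e-06, adjusted p = 0.604 with an estimated correlation). JUND fell furthest, followed by the zinc finger transcription factors EGR1, from 8.03 to 5.16 RPKM (log2 change −0.59), and EGR3, from 6.84 to 4.48 RPKM (−0.56). MYC was the member that rose.

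Replication-dependent histone genes fell as well. Of 13 tested, 9 fell, 0 rose and 4 did not pass (10 fell when adjusted over the list alone), with a median log2 change of −0.30 (camera adjusted p = 1.9e-06, adjusted p = 0.604 with an estimated correlation). HIST2H2BE fell from 36.9 ± 0.729 to 23.1 ± 1.16 RPKM (SD, n = 2 in each group; log2 change −0.67, limma adjusted p = 6.5e-06), and HIST1H4H, HIST1H3D and HIST1H3H fell by 0.53, 0.48 and 0.37. Histone genes have near-identical copies between which reads can be split, so their single values are uncertain. The median was −0.135 without the filter on low values.

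The epithelial, mesenchymal and basal markers that could be tested were lower on balance. Of 27 epithelial junction and keratin genes 11 fell, 0 rose and 16 did not pass (13 fell and 1 rose when adjusted over the list alone), with a median log2 change of −0.10 (camera adjusted p = 0.0018, adjusted p = 0.605 with an estimated correlation). MUC1, a transmembrane mucin, fell from 2.33 to 1.54 RPKM, CLDN1, a tight junction claudin, from 3.30 to 2.61 RPKM, and JUP, which encodes plakoglobin, from 98.3 to 85.0 RPKM. The list of transcription factors and mesenchymal genes of the epithelial-mesenchymal transition was covered in part. Of its 30 genes, 18 are among the deposited symbols, which end within the letter S, and 9 were tested. CDH2, SPARC and MMP2 were among those under the filter. Of the 9 tested genes 5 fell, 1 rose and 3 did not pass, and the counts adjusted over the list alone were the same. Their median was −0.25 (camera adjusted p = 0.044, adjusted p = 0.604 with an estimated correlation). The member that rose was SNAI2, while the collagen gene COL3A1 fell from 6.83 to 4.56 RPKM and the smooth muscle actin gene ACTA2 from 3.27 to 2.16 RPKM. COL3A1 and ACTA2 are also on the list of fibroblast markers, of which 4 were tested and 2, these genes, fell, with 1 rise and 1 that did not pass, also when adjusted over the list alone. The call of the epithelial-mesenchymal transition list ended without control siRNA library 2 (median −0.211) and without CEBPD siRNA library 2 (median −0.207). It also ended after a correction for GC content and length (camera adjusted p = 0.0624), and without the filter on low values the median was −0.0492. Markers of basal and triple-negative breast cancer lines, included as a check for other cells, fell in 7 of 11 members with 1 rise and 3 that did not pass, also when adjusted over the list alone (median −0.11, camera adjusted p = 0.012, adjusted p = 0.604 with an estimated correlation). ITGB4, the integrin β4 gene, fell from 11.2 to 8.18 RPKM and CAV1, the caveolin 1 gene, from 15.8 to 12.5 RPKM. The basal markers' median was −0.0691 without the filter on low values and −0.182 without control siRNA library 3.

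Interferon-stimulated and JAK/STAT3 signalling genes were lower on balance. Of 21 interferon-stimulated genes tested, 9 fell, 2 rose and 10 did not pass (11 fell and 3 rose when adjusted over the list alone), with a median log2 change of −0.13 (camera adjusted p = 0.0088, adjusted p = 0.605 with an estimated correlation). IRF9, a subunit of the transcription factor ISGF3, fell from 4.63 to 3.28 RPKM (log2 change −0.44), IFITM3, an antiviral membrane protein gene, from 38.4 to 30.7 RPKM (−0.32) and ISG15, which encodes a ubiquitin-like modifier, from 13.5 to 10.98 RPKM (−0.28). Of 19 JAK/STAT3 and IL6 signalling genes, 8 fell, 1 rose and 10 did not pass (9 fell and 1 rose when adjusted over the list alone), with a median of −0.08 (camera adjusted p = 0.016, adjusted p = 0.604 with an estimated correlation). STAT3 fell from 9.59 to 7.66 RPKM (log2 change −0.31). Both calls ended without control siRNA library 2 (adjusted p = 0.0791 and 0.0787), where ISG15 changed by −0.175. That of the interferon list also ended without the filter on low values (median −0.0882, adjusted p = 0.0733), where IFITM3 and ISG15 did not pass either (0.0654 and 0.114). The NF-kB and inflammatory cytokine list, with 4 falls, 1 rise and 5 of 10 members that did not pass, also when adjusted over the list alone, was not called (camera adjusted p = 0.12). LIF, a cytokine of the IL6 family, fell from 6.29 to 4.64 RPKM and NFKBIZ from 7.78 to 6.30 RPKM. Only 3 of the acute-phase and C/EBP-bound genes reached the filter, and SERPINA3 and PPARG (10.5 to 9.06 RPKM) fell while SERPINA1 did not pass (1.38 and 1.504 RPKM), also when adjusted over the list alone.

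Cholesterol synthesis genes fell in part. Of 23 tested, 8 fell, 1 rose and 14 did not pass (9 fell and 1 rose when adjusted over the list alone), and the median log2 change was −0.07 (camera adjusted p = 0.0069, adjusted p = 0.604 with an estimated correlation). DHCR24 and DHCR7, the last reductases of the pathway, fell from 71.6 to 51.5 RPKM (log2 change −0.47) and from 79.8 to 69.9 RPKM (−0.19). INSIG1, a sterol-sensing regulator, fell from 52.1 to 42.5 RPKM (−0.29).

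**Figure D3:**
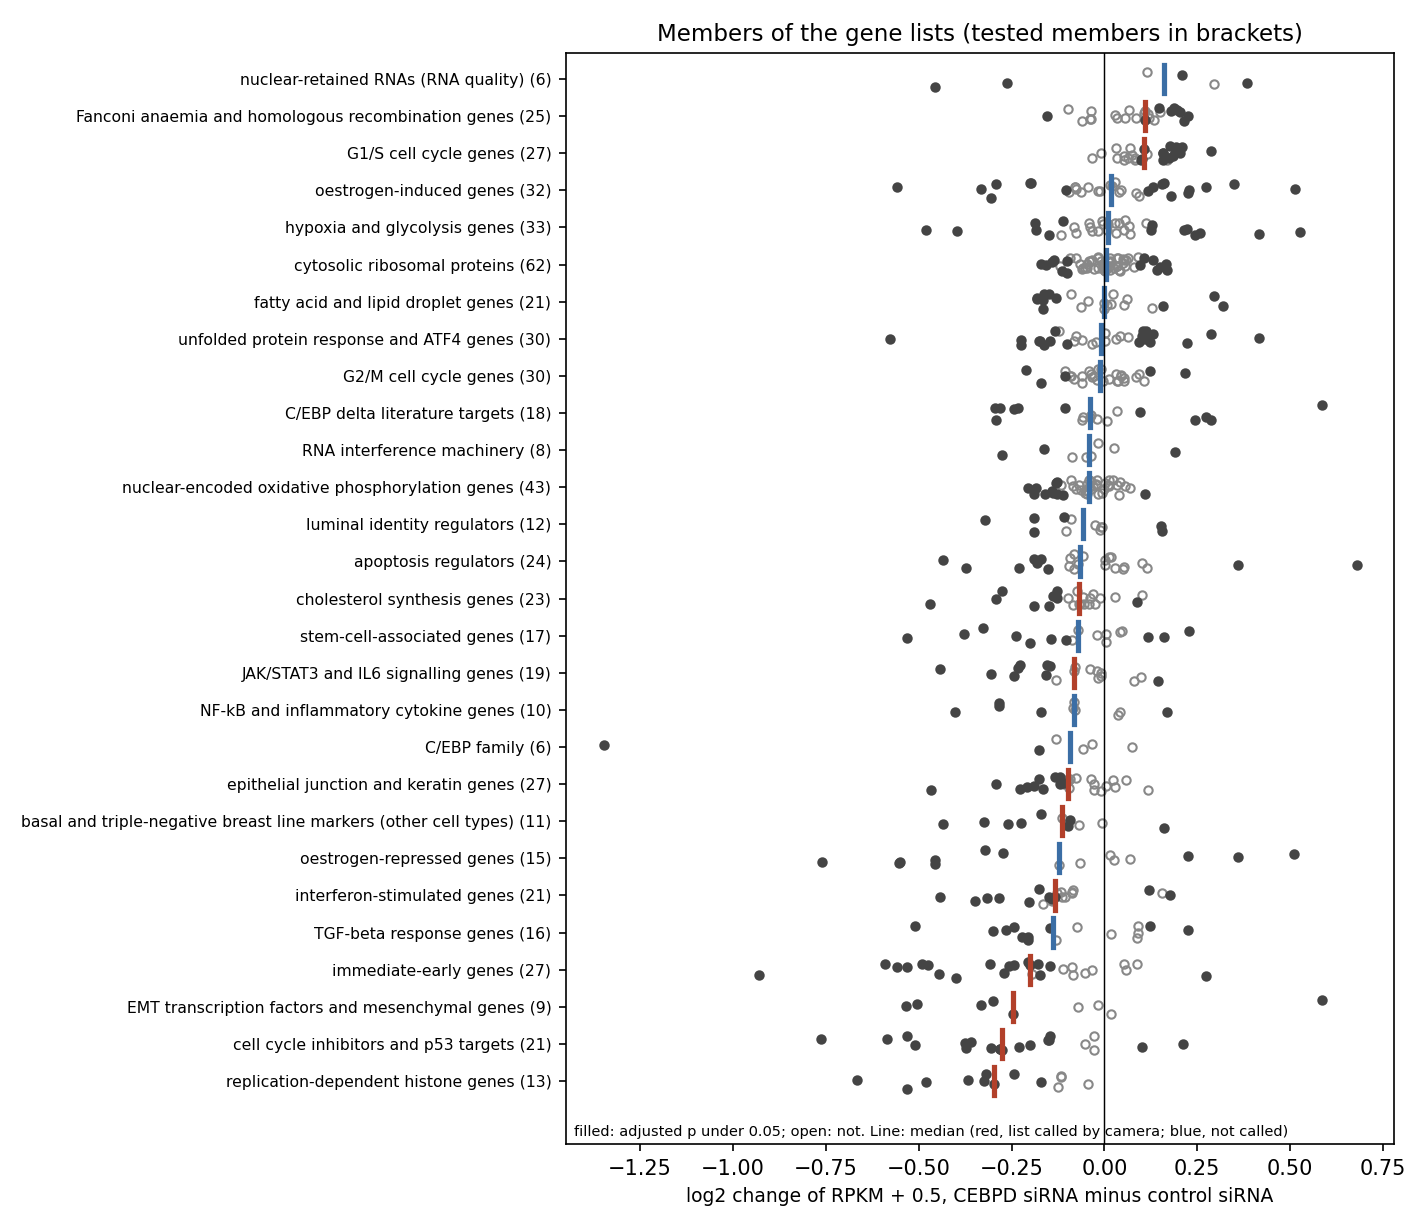
Log2 change of RPKM + 0.5, CEBPD siRNA minus control siRNA (horizontal axis), of the tested members of 28 gene lists, with the number of members in brackets. Filled points passed the threshold in limma, open points did not, and vertical lines are list medians (red where camera called the list, blue where not). The lowest medians are −0.30 for histone genes and −0.28 for cell cycle inhibitors and p53 targets, and 11 lists were called, 9 of them lower.

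Oestrogen-responsive lists were not called by camera. Of 32 oestrogen-induced genes 10 rose, 7 fell and 15 did not pass (12 rose and 8 fell when adjusted over the list alone, camera adjusted p = 0.66). The chemokine gene CXCL12 rose from 7.30 to 10.6 RPKM and the keratin gene KRT13 from 15.1 to 19.3 RPKM, whereas AREG, which encodes the EGF receptor ligand amphiregulin, fell from 11.7 to 9.19 RPKM. Of 15 oestrogen-repressed genes 7 fell, 3 rose and 5 did not pass (8 fell and 3 rose when adjusted over the list alone), with camera's adjusted p at 0.051. BCAS1 fell from 19.38 to 13.05 RPKM and SAT1, a polyamine acetyltransferase gene, from 11.98 to 8.02 RPKM, while SCNN1A, an epithelial sodium channel subunit gene, rose from 8.72 to 12.6 RPKM. Among 12 luminal identity regulators 2 rose, 4 fell and 6 did not pass (2 rose and 5 fell when adjusted over the list alone, camera adjusted p = 0.20). ERBB2 fell from 7.84 to 6.17 RPKM, and FOXA1, a pioneer factor of the oestrogen receptor, from 122 to 107 RPKM, a call that ended without the filter on low values (adjusted p = 0.0578). With an estimated correlation 0 of the 28 lists were called by camera, with 0.604 as the lowest adjusted p. That setting rests on the 2 residual degrees of freedom, so it could hardly call any list. The histone list, with an estimated correlation of −0.022, and the immediate-early list, with 0.408, both came to 0.604. It therefore does not tell which calls a correlation between genes would end. Among the called lists only the histone estimate lay below the preset of 0.01. The estimates were 0.309 for epithelial, 0.273 for interferon-stimulated, 0.215 for G1/S and 0.195 for Fanconi anaemia and recombination genes. Camera's p-values at the preset may be too small for lists so correlated. The rotation test fry, which does not compare a list with other genes, called 3 lists as moving one way, the cell cycle inhibitors and p53 targets, the histone genes and the oestrogen-repressed genes (adjusted p = 0.0456 for each).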

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

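The knockdown of CEBPD stayed past the threshold in all 16 alternatives computed for it. The number of genes changed stayed within 1.5 times of 3376 in all but 1, and 4 settings shared from 2221 to 2668 of those genes when a library was left out (2355 to 3018 called, of them 1032 to 1530 higher and 1290 to 1633 lower). Leaving out a library leaves a group with 1 sample, assumed to vary like the other group. The replicate block by the table's numbers called 3725 genes, and with the correction for GC content and length 4488, but same-numbered libraries did not deviate together (correlation 0.0476), so the numbers do not pair them. With the block CEBPB passed (adjusted p = 0.0038, and 0.0031 with the correction), and the Fanconi anaemia and recombination list was not called with block and correction (0.0648). The block and the correction alone (3904 genes) were chosen after seeing the data.

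With no filter on low values 1876 genes passed, 823 higher and 1053 lower, of which 1589 were among the 3376. More genes were tested there (16381) and the prior degrees of freedom were 2.22. The genes at least 1.5-fold apart numbered 140 (57 higher, 83 lower) with a pseudocount of 0.1 and 34 (11 and 23) with 1, since the pseudocount sets the fold of low genes. A mean RPKM of at least 2 left 13 higher. A 2-fold minimum left 3 at a pseudocount of 0.5, with 0 higher and 3 lower. Camera with an estimated correlation, which rests on the 2 residual degrees of freedom, called 0 lists and fry 3, against 11. With the preset correlation camera called 12 lists with values scaled to equal sums and 13 with median centring. It called 10 after the correction for GC content and length without a block. Some lists not called in the main setting were thus called in another.

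Of 128 named genes other than CEBPD that passed, 98 kept their call in every alternative computed for them, 84 of these in all 16, while 14 could be computed in only 14 or 15. No filter on low values ended 30 calls, and leaving out a library ended 15 in at least 1 setting. Genes that changed sign had not passed, and the cause was not tested. These were CDC27 (−0.0016) and NOTCH1 (0.00863) with the GC content and length correction, with or without the block, and with a library left out NOTCH1 (from −0.0415 to 0.00287), CEBPA (−0.117 to 0.00414), CEBPG (−0.0737 to 0.00598), FBXW7 (−0.00394 to 0.018) and S100A4 (−0.175 to 0.211, negative without control siRNA library 3 and, at −0.0276, without CEBPD siRNA library 3).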

Other observations

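The list of apoptosis regulators was not called. Of 24 apoptosis regulators 2 rose, 7 fell and 15 did not pass (3 rose and 8 fell when adjusted over the list alone, camera adjusted p = 0.20). Beside BCL2L11, BMF rose from 3.17 to 4.21 RPKM (log2 change 0.36), whereas BIK fell from 4.67 to 3.33 RPKM (−0.44) and the p53 target BBC3, which encodes PUMA, from 7.67 to 5.80 RPKM (−0.37). Of 17 stem-cell-associated genes 3 rose, 7 fell and 7 did not pass, also when adjusted over the list alone (camera adjusted p = 0.13). ALDH1A3, an aldehyde dehydrogenase gene, fell from 16.4 to 11.2 RPKM, the Notch ligand gene JAG1 from 1.86 to 1.32 RPKM and the transcription factor gene SOX4 by 0.33 on the log2 scale. Among 16 TGF-β response genes 2 rose, 8 fell and 6 did not pass (3 rose and 9 fell when adjusted over the list alone, camera adjusted p = 0.11), with SERPINE1, the gene of plasminogen activator inhibitor 1, at 1.28 and 0.949 RPKM (limma adjusted p = 0.0018).

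Stress and metabolic lists other than cholesterol synthesis were not called by camera. Of 33 hypoxia and glycolysis genes 8 rose, 6 fell and 19 did not pass, also when adjusted over the list alone (camera adjusted p = 0.52). ALDOC, an aldolase gene, rose from 1.93 to 3.001 RPKM and DDIT4 from 62.1 to 82.9 RPKM, while PFKFB3, a regulator of glycolysis, fell from 20.3 to 15.3 RPKM. Of 30 genes of the unfolded protein response and ATF4, 10 rose, 9 fell and 11 did not pass (10 rose and 12 fell when adjusted over the list alone, camera adjusted p = 0.91). NUPR1 fell from 3.19 to 1.97 RPKM and MANF rose from 15.3 to 18.8 RPKM. Fatty acid and lipid droplet genes had 3 rises, 7 falls and 11 that did not pass of 21 (4 and 7 when adjusted over the list alone, camera adjusted p = 0.66), oxidative phosphorylation genes 1, 10 and 32 of 43 (0 and 10, 0.054), ribosomal protein genes 7, 7 and 48 of 62 (5 and 3, 0.83) and genes of the RNA interference machinery 1, 2 and 5 of 8 (the same counts, 0.49). Of 6 nuclear-retained RNAs, a check of RNA quality, 2 rose, 2 fell and 2 did not pass (3 rose and 2 fell when adjusted over the list alone, camera adjusted p = 0.70). NEAT1 fell from 103 to 74.7 RPKM and MALAT1 from 24.7 to 20.5 RPKM, while RMRP rose from 1.91 to 2.61 RPKM and SNHG1 from 58.8 to 68.0 RPKM. Without the filter on low values MALAT1 and RMRP did not pass (limma adjusted p = 0.0682 and 0.19). The even count does not show that RNA quality was equal between groups. Markers of fibroblasts, leukocytes and hepatocytes were too few for a set test. Of 4 fibroblast genes 1 rose, 2 (COL3A1 and ACTA2) fell and 1 did not pass, of 2 leukocyte genes 1 fell and 1 did not pass, and the 1 hepatocyte gene did not pass, with the same counts when adjusted over the list alone.

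In what follows, the tests that use the 3 words of the 3′ UTRs were chosen after the words had been seen, as was the use of a list's call after the GC correction. The test of the CEBPD transcript's own 8-base word was chosen after the medians of the 4 extensions were known. The cell cycle inhibitors and p53 targets kept a median log2 change of −0.256 (95% bootstrap interval −0.317 to −0.126) after a correction for GC content and transcript length, with a camera adjusted p of 7.3e-06, which argues against these trends as the whole source, although the interval just exceeds 50% of the uncorrected median (−0.138), the bound set beforehand. The 18 p53 targets had a median 0.25 below that of the other 3 inhibitors (difference −0.25, exact permutation p = 0.159, two-sided), too few genes to say that they differ. The 3 words occurred in 7 of the 21 members, and the 14 without them had a median of −0.191 (interval −0.282 to −0.041), so a direct seed match may contribute and stays open. A response to the loss of C/EBPδ also stays open, since every CEBPD siRNA library had both.

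The immediate-early and histone genes together kept a median of −0.192 after the same correction (interval −0.293 to −0.109, 39 members), and both lists stayed called (adjusted p at most 7.02e-05), which argues against GC content and length as the whole source. The interval lies just beyond 50% of the uncorrected median of these members (−0.103) but not of all 40 (−0.112), so that bound is met narrowly at most. A lower yield of transcripts without introns as the main source is argued against by 341 single-exon genes outside the lists. Their median was −0.05 (interval −0.072 to −0.028) against the same −0.112. These genes were taken at any length, so a lower yield of short ones was not tested. Of 37 members with a searched 3′ UTR, 27 without the words had a median of −0.174 (interval −0.297 to −0.088), which leaves a direct seed match open, and JUND, EGR3 and BTG2 are among the 10 with a word. A response to C/EBPδ stays open too.

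The many small changes were not reduced by the GC and length correction, after which 3904 genes passed. A candidate source for some of the falls is silencing of other transcripts by the seed of an siRNA. Among 16115 words of 7 bases in the 3′ UTRs of 8989 genes, GAGAGAA had the lowest statistic relative to words of the same base composition, −12.61, where 100 permutations of genes reached −4.86 and the lowest word unrelated to it −4.74. A direct match to the 3 lowest words in the 3′ UTR is not the source of most falls. Of the genes that fell 44.38% hold one of them, and 29.7% of the genes that did not pass hold one as well. Further words also lay below the permutations, among them GAGAGAG (−6.49) and GAGAGAT (−5.97). These, shorter matches and matches outside the 3′ UTR were not counted, so a seed as the source of most falls is not excluded. With 3 splits of the 4 libraries chance cannot be given a share under 0.05, and as many genes passed in 1 of the 3, the real one, with 0 genes as the highest of the others. The other splits mix control and CEBPD siRNA libraries, so a difference between the groups from any source widens their spread. Their 0 therefore does not tell where the difference came from.

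Whether the word belongs to the CEBPD siRNA was examined in the CEBPD transcript. It holds GAGAGAA at 1 place, in the 3′ UTR at 48649695 to 48649701 on chromosome 8 of GRCh37. Of 866 genes with a 3′ UTR within 25% of its length (398 nt), 7.6% hold any of the 3 words there. The search covered the whole CEBPD transcript of 1252 nt, so that share understates how often such a search finds a word. Only the base before the word was varied, and extensions by a base after it were not tested. Genes with the 8-base word AGAGAGAA, the lowest of these 4 extensions, had a median of −0.058 (834 genes). Those with the 7-base word alone had −0.02 (885 genes), a difference of −0.037 (permutation p = 0.0001, two-sided, not adjusted for the choice among 4). AGAGAGAA also holds AGAGAGA, another of the 3 words picked on these same changes, so its larger fall follows in part from that choice. The extension AGAGAGAA is not the one in CEBPD, which holds CGAGAGAA and neither AGAGAGA nor TGAGAGA. The 74 other genes with CGAGAGAA had a median of −0.047 against −0.039 for 1644 genes with the 7-base word and other bases before it, a difference of −0.008 (permutation p = 0.743, two-sided), which does not tell the CEBPD site from the rest. An siRNA seed acting beyond CEBPD stays a hypothesis. Its match to CEBPD covers 7 bases and not the base before them that went with the largest fall, while the base after them was not examined. The siRNA sequences needed to decide it are not given in the sources used here. An endogenous regulator that binds the same word could give the same pattern. No word stood out among genes that rose, where the highest statistic was 3.44 and permutations reached 4.83.

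A loss of C/EBP-bound promoters was tested as another hypothesis for the genes that fell. The C/EBP site lay between 500 bases before and 100 after the start of 13 of 1627 genes that fell (0.8%) and 26 of 4966 genes with an unadjusted p of 0.05 or more (0.52%), an odds ratio of 1.53 (Fisher's exact p = 0.262, two-sided). As large an excess came from 0 of 20 shuffled sites, but the sites are too few for the hypothesis to be accepted or excluded.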
